A study of Homo sapiens with 6 samples.

How the data were processed

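RNA sequencing was performed on 6 libraries of total RNA from T24 cells, an established line from a human bladder carcinoma, with 3 libraries in each of 2 groups. Per the labels' protocols, the cells were stably transduced by lentivirus with the vector (VEC) or with a constitutively active mutant of RhoC (Q63E), selected with puromycin, and sequenced from Illumina TruSeq libraries on a HiSeq X instrument. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 and the human build GRCh38.p10, with no role or order. The counting program, the annotation and any filter are not given in the sources used here.

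The authors deposited 1 table per library with 58882 rows and 1 value per row, to 2 decimals. Of these rows, 58233 carried an Ensembl gene identifier. The other 649 were assembled loci with no gene name, and they held between 0.274% and 0.511% of a library's summed value. The deposited values are taken here as FPKM, although neither the file headers nor the labels name the unit. Short genes such as MT-ATP8 ranked at the top, as they do after division by transcript length. The totals of 726929 to 769026 differed between libraries, so the listed values are neither TPM nor CPM over these rows. Steps that would show whole reads were searched for among genes of 200 to 3000 bases with low values. At best 25.0% to 30.4% of the values per library fell within 0.1 of a whole number, against 20% if there were no steps, so read counts were not recovered. The depth of each library is therefore unknown, and no counting interval or detection floor is given. A value of exactly 0 can be a failed estimate in such files, so a gene at 0 is described as listed at 0.

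The design fixed before the data were examined assumed read counts and named limma on log2 values as the replacement for normalized values, and this replacement was used. Values were transformed as log2(value + 1) and genes with a mean of at least 1 over the 6 libraries were tested, which left 13346 genes, 11568 of them protein-coding. The test was limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, two-sided, on group alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 differences of value + 1 between Q63E and VEC, and they understate the change of low genes. Linear folds in the text are ratios of group means. Symbols came from a gene table that paired 57392 of the Ensembl identifiers, and coordinates and gene types from GENCODE release 29 on GRCh38, which held 57895 of them. The authors' values per gene do not state a strand, so reads of overlapping or antisense genes, and of near-identical copies, may be shared between rows. Values for the transduced and the cell's own RHOC are 1 row and are not told apart.

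A set of 39 gene lists was fixed before the data were examined. The lists described here cover MRTF-SRF, YAP-TAZ, immediate early, mesenchymal, epithelial and urothelial genes, matrix proteases, extracellular matrix, integrins and angiogenic factors. They also include NF-kB and cytokine, interferon-stimulated, antigen presentation, DNA replication, mitosis, p53, apoptosis, hypoxia, glycolysis, cholesterol, fatty acid, unfolded protein, ATF4, TGF-beta, NRF2, Notch and Wnt, and stem cell-associated genes. Further ones are autophagy and lysosome, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal protein, proteasome and histone genes, and markers of leukocytes, fibroblasts and endothelium. Results of 3 of the 39 lists are not given. The 36 lists with at least 5 tested members were tested with camera in limma, two-sided, at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. The same lists were run with an estimated correlation and with fry. While camera sets the members of a list against all other genes, fry tests them against no change, so its calls answer another question.

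Genes are named by a rule fixed before the data were examined. It takes RHOC, RHOA and RHOB. It then takes the 8 genes with the largest rise and the 8 with the largest fall, and the 4 risen and 4 fallen genes with the smallest p not yet named. These had to be protein-coding, to pass the threshold and the minimum mean, and to have all 3 Q63E libraries on one side of all 3 VEC libraries. For each list it allows up to 4 members past the threshold with the largest change, or the members with the highest mean if fewer than 2 passed. Genes named outside this rule are said to be so where they appear.

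The same steps were tested on simulated data made from these libraries, with 13141 genes in the fit. At 1.25-fold 20.0% of the changed genes were recovered, at 1.5-fold 50.0%, at 2-fold 73.3% and at 4-fold 91.5%. Only 45 to 50 genes were changed at each fold, a far smaller share than the 25.3% called in the data. The adjusted threshold depends on that share, so these rates need not hold for the data. Of 115 calls, 6 were on unchanged genes (5.22%). In a second simulation the list that had been shifted had an adjusted p of 3.12e-44 in camera (0.00306 with an estimated correlation), and 0 of the unchanged lists were called. Genes were drawn independently of one another in both simulations. The lack of false list calls therefore does not carry over to real lists, whose members can be correlated.

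The analysis was repeated with 3 other scalings, no filter and another filter on low values, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, a threshold of 0.01, a test against a 1.5-fold change and lists without shared members. DESeq2 and limma-voom had been planned for counts and were not run. These had been fixed before the data were examined. After the data were seen, 4 more were added. They include the loci without a gene name, leave out genes listed at 0 in any library, leave out the genes of chromosome segments with shifted expression, or subtract the median deviation of each such segment in each library. These segments were found from medians of windows of 50 neighbouring tested protein-coding genes, joined where the median was 0.25 or more in size.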

Results

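The series compares T24 cells, an established human bladder carcinoma line, that stably carry a constitutively active mutant of RhoC (Q63E, n = 3 libraries) with T24 cells that carry the vector (VEC, n = 3). The question the design poses is which transcripts differ when active RhoC is overexpressed. Summed values per library ran from 726929 to 769026, and between 20792 and 21379 rows lay above 0. Across genes, log2 values correlated at r = 0.968 to 0.976 within a group and at r = 0.953 to 0.958 between groups. The first principal component held 40.7% of the variance and separated the groups. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

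RHOC (ENSG00000155366, chromosome 1 from 112701106 to 112707434 on the minus strand of GRCh38) had a value of 227 ± 8.27 (SD, n = 3) in VEC and 1746 ± 22.3 (SD, n = 3) in Q63E. This is a 7.69-fold difference, with a log2 fold change of 2.94 (SE 0.036) and an adjusted p of 3.12e-07 in limma. Each of the 3 Q63E libraries lay above each VEC library. Its closest relatives moved less: RHOA went from 259 ± 7.80 to 314 ± 2.77 (log2 fold change 0.28, adjusted p = 0.00206) and RHOB from 19.4 ± 2.12 to 13.9 ± 0.645 (log2 fold change −0.44, adjusted p = 0.0141). RHOA lies in a part of chromosome 3 where most genes were higher in Q63E. After subtraction of that segment's median its log2 fold change was −0.06 (adjusted p = 0.224), while that of RHOC, which lies in a raised segment of chromosome 1, was 2.67.

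**Figure D1:**
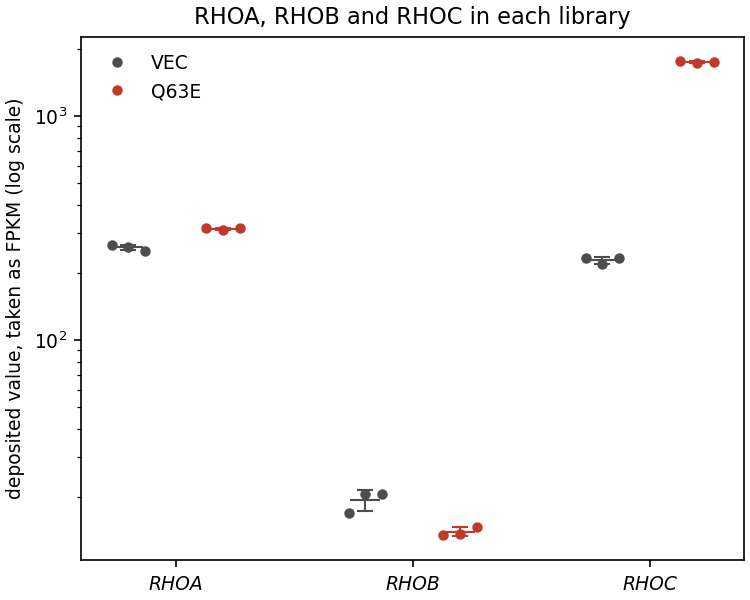
Deposited values (taken as FPKM, log axis) of RHOA, RHOB and RHOC in each library, with points for the 3 VEC and 3 Q63E libraries and bars for the mean ± SD. RHOC stands at 227 in VEC and 1746 in Q63E.

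Of 13346 genes tested, 3383 (25.3%) passed the threshold in limma, 1510 higher and 1873 lower in Q63E. A change of at least 2-fold was seen for 324 of them, 131 higher and 193 lower. Among protein-coding genes, 1384 were higher and 1789 lower. The 2 groups did not overlap for 5853 genes (43.9%, against 10% by chance with 3 against 3). Without Q63E replicate 3, 994 genes were higher.

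Besides RHOC, the largest rises among protein-coding genes were those of 7 genes. KRT19, a keratin of simple epithelia, went from 5.67 ± 0.393 to 161 ± 1.85 (28.4-fold, log2 fold change 4.61, adjusted p = 3.12e-07). TMPRSS15, which encodes the protease enteropeptidase, was near absent in VEC (0.02, with 1 library listed at 0) and at 22.6 ± 1.71 in Q63E. NPPB, the precursor of a natriuretic peptide, rose from 0.437 ± 0.221 to 17.2 ± 2.005. SERINC2 rose from 4.52 ± 0.582 to 59.2 ± 2.23, and DMKN (dermokine) from 3.08 ± 0.281 to 40.0 ± 6.07. The kinase gene STK26 rose 12.5-fold to 15.8 ± 0.501 and IGFBP1, an insulin-like growth factor binding protein, 8.91-fold to 15.9 ± 1.44. The risen genes with the smallest p not yet named were F3 (tissue factor, which starts blood clotting), PHEX, IGFBP3 and DSP (desmoplakin of desmosomes). F3 went from 257 ± 3.62 to 753 ± 11.6, PHEX from 9.53 ± 0.204 to 32.5 ± 0.488, IGFBP3 from 55.7 ± 2.08 to 186 ± 10.8 and DSP from 8.29 ± 0.240 to 27.3 ± 0.438.

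The largest falls included a chemokine, a Wnt receptor and a matrix protein. CXCL6, a neutrophil-attracting chemokine, fell from 104 ± 5.89 to 2.33 ± 1.04 (log2 fold change −5.01, adjusted p = 4.47e-05). SEPTIN1 fell from 32.4 ± 0.634 to 0.807 ± 0.512, and CYB5R2, a cytochrome b5 reductase gene, from 11 ± 0.980 to 0.153 ± 0.0351. TMC2 had values of 13.5, 15.0 and 15.6 in the VEC libraries and was listed at 0 in all 3 Q63E libraries. FZD8, a receptor for Wnt proteins, fell from 11.3 ± 0.539 to 0.660 ± 0.114. The centrosomal gene CEP350 fell from 69.7 ± 0.978 to 9.01 ± 0.851, TNC (tenascin C of the extracellular matrix) from 11.3 ± 1.13 to 1.27 ± 0.424 and CLEC11A from 33.9 ± 1.16 to 5.63 ± 0.626. The fallen genes with the smallest p not yet named were CXCL1 (1601 ± 50.2 to 368 ± 25.5), FEZ1 (61.4 ± 4.11 to 12 ± 0.437), the interferon-induced gene IFI44 (32.6 ± 1.06 to 8.97 ± 0.0666) and PACS1 (87.4 ± 2.83 to 32.1 ± 0.786).

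**Figure D2:**
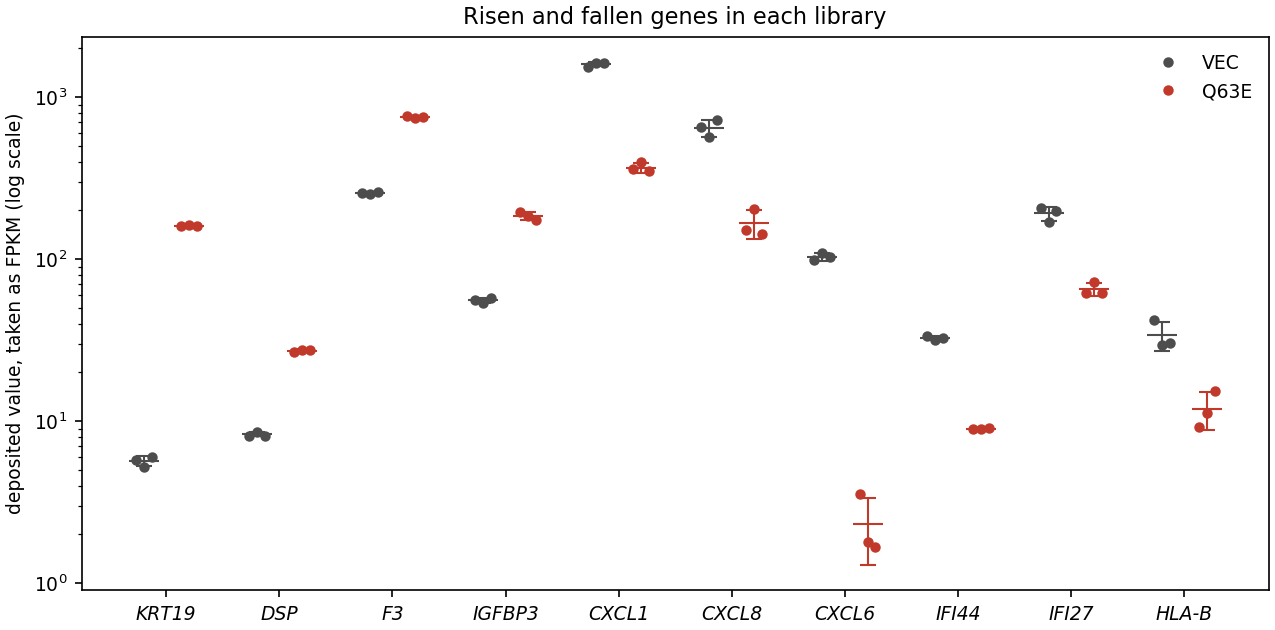
Deposited values (taken as FPKM, log axis) of 10 named genes in each library, with points for the 3 VEC and 3 Q63E libraries and bars for the mean ± SD. KRT19, DSP, F3 and IGFBP3 lie higher in all Q63E libraries, and CXCL1, CXCL8, CXCL6, IFI44, IFI27 and HLA-B lower.

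Changed genes were not spread evenly over the chromosomes. In 8 segments, chosen after the values were seen, most neighbouring genes moved the same way: these held 1640 tested genes (12.3%) and 847 of the 3383 changed genes (25.0%). Inside them 51.6% of the tested genes passed the threshold, and outside them 21.7%. Because the segments were picked by their shift in these same values, a higher share inside was built in. Lower in Q63E were chromosome 4 from 0.1 to 145.7 Mb (median log2 fold change −0.41, 310 of 360 genes below 0) and chromosome 10 from 0.1 to 42.8 Mb (−0.39, 106 of 121). Chromosome 22 from 32.8 to 50.5 Mb had −0.42 (136 of 172), chromosome 21 from 5.1 to 45.5 Mb −0.34 (115 of 141), chromosome 8 from 0.2 to 52.7 Mb −0.30 (153 of 181) and chromosome 9 from 14.6 to 101.4 Mb −0.28 (200 of 257). Higher were chromosome 3 from 3.1 to 66.4 Mb (0.34, 292 of 327 above 0) and chromosome 1 from 103.6 to 119.7 Mb (0.30, 70 of 81). The median deviation from each gene's VEC mean in the chromosome 4 segment was −0.001 ± 0.00484 in VEC and −0.390 ± 0.00157 in Q63E (SD, n = 3 each). Outside the segments, 1273 genes were higher and 1263 lower, and refitted without the segment genes the test called 1172 higher and 1162 lower. Smaller regional shifts remain there. A window on chromosome 11 from position 118359585 had a median of −0.232 (39 of 50 genes lower). Another, on chromosome 3 from position 185282941, had −0.231 (41 of 50 lower). The largest window median in 200 shuffles of gene order was 0.215 in size. Of the 324 changes of at least 2-fold, 67 lay inside and 257 outside. With the segment medians subtracted, 19 of the 45 genes inside that met the naming rule no longer passed. Those that still passed include TMPRSS15 (log2 fold change 4.86), CXCL6 (−4.62), FZD8 (−2.48), TIMP3 (−1.66), CA9 (1.62), STC1 (−1.14), WNT5A (0.77), NDUFA6 (−0.45), PPARG (0.31), WDR1 (−0.30), CXCL1 (−1.73), CXCL8 (−1.57), CXCL3 (−1.45) and HMOX1 (0.93).

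**Figure D3:**
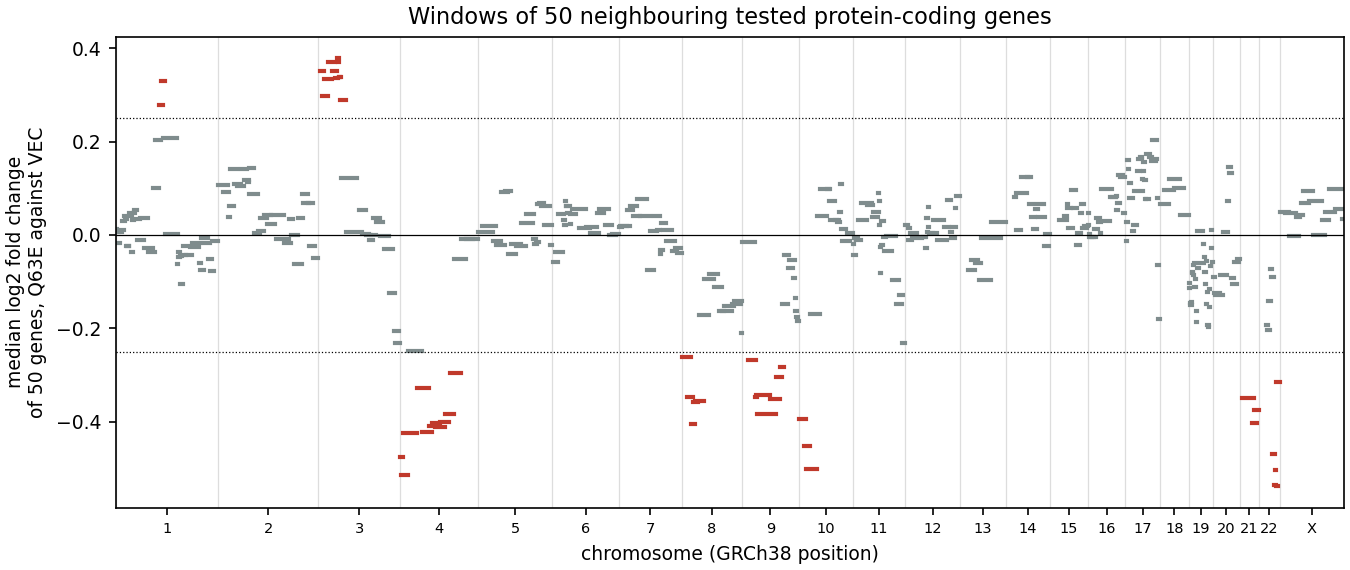
Median log2 fold change (vertical axis, Q63E against VEC) of windows of 50 neighbouring tested protein-coding genes along the chromosomes (horizontal axis, GRCh38 position), with red for windows at or past the dotted lines at 0.25 and −0.25 and grey for the rest. Of 426 windows, 47 are red, and they lie on chromosomes 1, 3, 4, 8, 9, 10, 21 and 22.

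Of 36 gene lists, 12 passed the threshold in camera, 6 higher and 6 lower in Q63E. With an estimated correlation 0 lists passed in camera (lowest adjusted p = 0.0853). The estimate was 0.8 for ribosomal protein, 0.509 for mitochondrially encoded and 0.366 for NF-kB and cytokine genes, above the preset 0.01. It lay below 0.01 for epithelial (−0.0157), antigen presentation (−0.03), DNA replication (−0.00177) and unfolded protein genes (−0.0313). For these lists a higher correlation of their own members does not account for the lost call. In the simulation, the shifted list went from an adjusted p of 3.12e-44 to 0.00306 in camera with an estimated correlation. Its genes had been drawn independently, so this setting weakens calls without correlated members too. The 0 lists are therefore not evidence that members of the lists are correlated. With fry, which tests a list against no change rather than against other genes, 25 passed. Epithelial junction and keratin genes were higher: of 21 tested members 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.61 and an adjusted p of 7.18e-09 (adjusted p = 0.0853 with an estimated correlation). Besides KRT19 and DSP, OCLN (occludin of tight junctions) rose from 1.05 ± 0.394 to 3.68 ± 0.803 and ESRP2, an epithelial splicing regulator, from 0.777 ± 0.164 to 2.66 ± 0.331. Of its 21 members, 1 lay in a shifted segment.

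Hypoxia response genes were higher, with 14 risen and 2 fallen of 30 (18 and 3 adjusted over the list alone), a median of 0.19 and an adjusted p of 3.85e-05 in camera (adjusted p = 0.559 with an estimated correlation). CA9 (carbonic anhydrase 9) rose from 2.88 ± 0.580 to 8.76 ± 1.19, LOX (lysyl oxidase) from 29.8 ± 2.75 to 62.4 ± 4.08 and ADM (adrenomedullin) from 55.1 ± 7.06 to 108 ± 0.739, while STC1 (stanniocalcin 1) fell from 12.8 ± 0.360 to 3.98 ± 0.248. Glycolysis genes had 10 risen and 3 fallen of 21 (11 and 4 adjusted over the list alone), a median of 0.14 and an adjusted p of 0.0153 (adjusted p = 0.62 with an estimated correlation). ENO2 (enolase 2) rose from 116 ± 4.06 to 182 ± 8.96 and PGK1 from 760 ± 50.9 to 951 ± 64.8. The rise of PGK1 did not pass without VEC replicate 3 or with the replicate number as a block. PFKL and PFKFB3 fell, from 105 ± 3.33 to 80.7 ± 2.11 and from 174 ± 6.45 to 139 ± 10.3. Both lie in lowered segments, and with the segment medians subtracted their log2 fold changes were −0.04 (adjusted p = 0.538) and 0.09 (adjusted p = 0.354). Of the hypoxia list 7 members lay in shifted segments, and of the glycolysis list 4.

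Unfolded protein response genes had 10 risen and 2 fallen of 22 (12 and 3 adjusted over the list alone), a median of 0.14 and an adjusted p of 0.00978 in camera (adjusted p = 0.26 with an estimated correlation). EDEM1 rose from 15.6 ± 0.403 to 23.6 ± 0.476, MANF from 68.3 ± 2.58 to 98.1 ± 0.879, SEL1L from 17.3 ± 1.002 to 23.9 ± 0.225 and HERPUD1 from 46.4 ± 6.59 to 62.2 ± 1.66. EDEM1 and MANF lie in the raised segment of chromosome 3, and with its median subtracted their log2 fold changes of 0.56 and 0.52 were 0.22 and 0.18 (adjusted p = 0.0229 and 0.0215). The rise of HERPUD1 did not pass without VEC replicate 3, without Q63E replicate 1, 2 or 3, or with no filter on low values. YAP-TAZ target genes had 9 risen and 2 fallen of 25 (9 and 2 adjusted over the list alone), a median of 0.08 and an adjusted p of 0.0310 (adjusted p = 0.62 with an estimated correlation). F3 and IGFBP3 led this list, CCN1 rose from 206 ± 25.7 to 330 ± 42.2, and NT5E fell from 44.8 ± 2.41 to 22.4 ± 0.287. The call was lost without VEC replicate 1 (adjusted p = 0.0996), without Q63E replicate 3 (0.0590), without shared members (0.0529) and without the shifted segments (0.0620).

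Cytoplasmic ribosomal protein genes had 14 risen and 3 fallen of 60 (18 and 5 adjusted over the list alone), a median of 0.12 and an adjusted p of 0.00978 in camera (adjusted p = 0.774 with an estimated correlation). The 4 largest changes were rises of RPL15 (1358 ± 88.1 to 1904 ± 58.2), RPSA (1549 ± 46.0 to 2143 ± 69.5), RPL32 (1143 ± 99.5 to 1532 ± 60.6) and RPL14 (599 ± 26.7 to 802 ± 11.1). All 4 lie in the raised segment of chromosome 3, and with its median subtracted none passed (adjusted p = 0.105, 0.0638, 0.417 and 0.209). The list call was lost without VEC replicate 2 (adjusted p = 0.218), without Q63E replicate 2 (0.0532) and without the shifted segments (0.0571). Tested against no change with fry, the list did not pass (adjusted p = 0.235).

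NF-kB and inflammatory cytokine genes were lower, with 27 of 31 fallen and 0 risen (27 and 1 adjusted over the list alone), a median log2 fold change of −0.62 and an adjusted p of 6.95e-14 in camera (adjusted p = 0.352 with an estimated correlation). The largest falls were those of neutrophil-attracting chemokines. Besides CXCL6 and CXCL1, CXCL8 fell from 649 ± 78.4 to 166 ± 33.5 and CXCL3 from 46.8 ± 3.71 to 12.5 ± 2.92. These 4 genes lie in the lowered segment of chromosome 4, whose median of −0.41 is smaller than their falls. Of the 23 members outside the shifted segments 20 fell, with a median of −0.60, and the list passed without the segment genes (adjusted p = 3.83e-11).

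Interferon-stimulated genes were lower, with 19 fallen and 1 risen of 35 (23 and 1 adjusted over the list alone), a median of −0.56 and an adjusted p of 2.18e-08 in camera (adjusted p = 0.165 with an estimated correlation). OASL, an antiviral oligoadenylate synthetase-like gene, fell from 8.87 ± 0.378 to 1.53 ± 0.357. IFI27 fell from 192 ± 19.3 to 65.4 ± 6.15 and IFIT2 from 13.6 ± 0.397 to 3.94 ± 0.231. Of the 31 members outside the shifted segments 15 fell, with a median of −0.48. Antigen presentation genes had 10 fallen and 0 risen of 19 (10 and 0 adjusted over the list alone), a median of −0.28 and an adjusted p of 0.0164 (adjusted p = 0.265 with an estimated correlation), and 0 of them lay in a shifted segment. HLA-B fell from 34.0 ± 6.84 to 12 ± 3.13, TAP1, a peptide transporter, from 12.3 ± 1.02 to 8.81 ± 0.652 and HLA-DPA1 from 13.6 ± 0.0971 to 9.52 ± 1.64. The fall of TAP1 did not pass with the replicate number as a block. That of HLA-DPA1 did not pass when VEC replicate 1, 2 or 3 or Q63E replicate 2 or 3 was left out, nor with no filter on low values. HLA genes are near-identical to one another in parts, so their reads can be shared.

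DNA replication genes had 13 fallen and 3 risen of 45 (14 and 4 adjusted over the list alone), a median of −0.13 and an adjusted p of 0.0177 in camera (adjusted p = 0.26 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, fell from 235 ± 8.47 to 175 ± 6.22 and CDC45 from 48.9 ± 5.18 to 35 ± 0.475. CHAF1B fell from 13.8 ± 0.667 to 8.26 ± 0.917 and SLBP from 80.1 ± 1.69 to 54.2 ± 3.20, both in lowered segments. With the segment medians subtracted CHAF1B had a log2 fold change of −0.35 in place of −0.68 (adjusted p = 0.0374). SLBP did not pass (adjusted p = 0.0723), nor did the list (adjusted p = 0.0741). Genes of G2/M and mitosis had 14 fallen and 1 risen of 46 (15 and 1 adjusted over the list alone), a median of −0.06 and an adjusted p of 0.0119 (adjusted p = 0.62 with an estimated correlation). KIF4A, a mitotic kinesin, fell from 67.3 ± 0.675 to 31.6 ± 0.737. GTSE1 (94.1 ± 6.28 to 60.4 ± 4.03), MELK (75.8 ± 2.53 to 52.3 ± 0.985) and CCNA2 (cyclin A2, 58.3 ± 1.52 to 40.4 ± 1.31) fell too, all in lowered segments. After subtraction of the segment medians MELK had a log2 fold change of −0.25 in place of −0.53 (adjusted p = 0.00723), and GTSE1 (adjusted p = 0.0991) and CCNA2 (0.0997) did not pass.

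**Figure D4:**
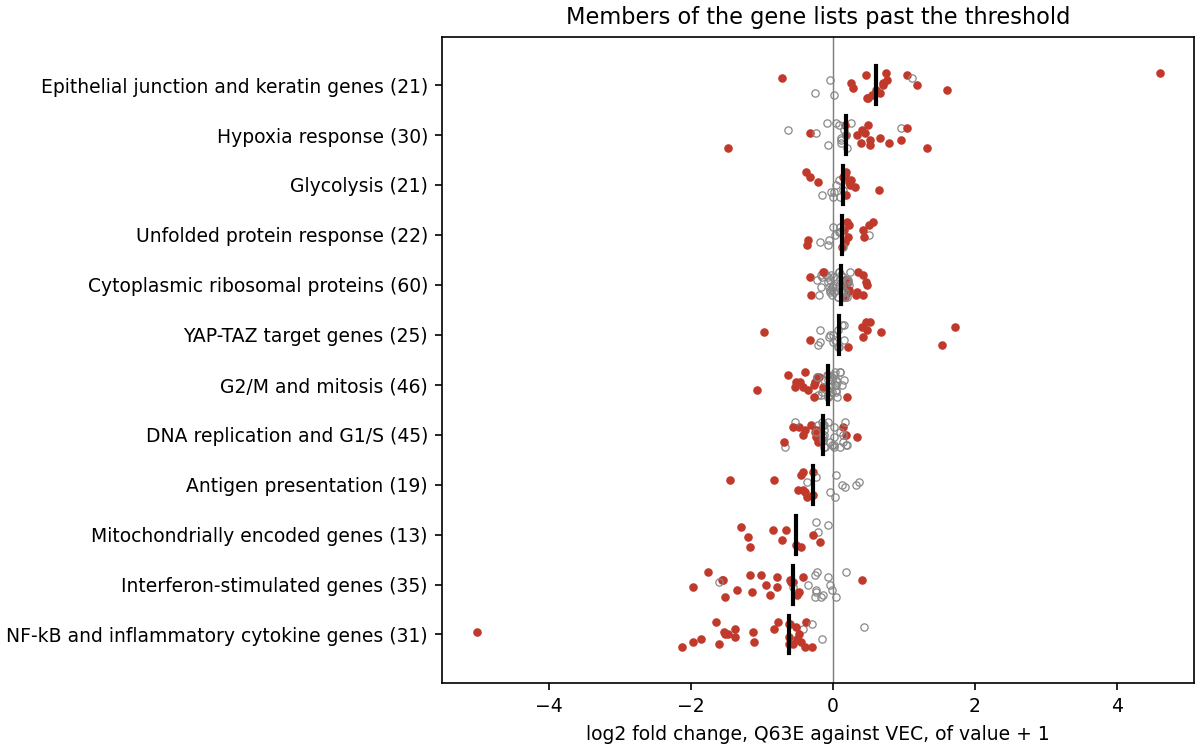
Log2 fold change of value + 1 (horizontal axis, Q63E against VEC) for each tested member of the 12 gene lists past the threshold (vertical axis, with the number of tested members), filled red where the gene passed and open grey where it did not, with a black line at the list's median. The medians run from −0.62 for NF-kB and inflammatory cytokine genes to 0.61 for epithelial junction and keratin genes.

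Mitochondrially encoded genes were lower, with 10 fallen and 0 risen of 13 (11 and 0 adjusted over the list alone), a median of −0.52 and an adjusted p of 1.21e-07 in camera (adjusted p = 0.443 with an estimated correlation). They held 8.5% ± 0.507 of a library's summed value in VEC and 5.43% ± 0.376 in Q63E (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). The falls were unequal along the mitochondrial chromosome. MT-ATP8 (positions 8366 to 8572), MT-ATP6 (8527 to 9207) and MT-CO3 (9207 to 9990) are neighbours and had log2 fold changes of −1.16, −1.19 and −1.29. MT-CO3, a subunit of cytochrome c oxidase, fell from 7020 ± 344.2 to 2864 ± 204. The median of the other 10 genes was −0.36, and they ran from −0.83 (SE 0.072) for MT-ND2 to −0.07 (SE 0.058) for MT-ND6. MT-ND6 is the 1 gene on the other strand and is named outside the rule for naming genes. Reads of the overlapping MT-ATP8 and MT-ATP6 can be shared. Nuclear oxidative phosphorylation genes did not pass in camera (adjusted p = 0.0579), with 8 fallen and 3 risen of 48 (8 and 3 adjusted over the list alone). NDUFA6, in the lowered segment of chromosome 22, fell from 125 ± 4.15 to 68.0 ± 3.07 and SDHC from 179 ± 9.11 to 106 ± 2.89. That list passed in 6 of 17 alternative fits, with adjusted p-values from 0.00853 (without VEC replicate 2) to 0.497, and not with an estimated correlation (adjusted p = 0.774).

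**Figure D5:**
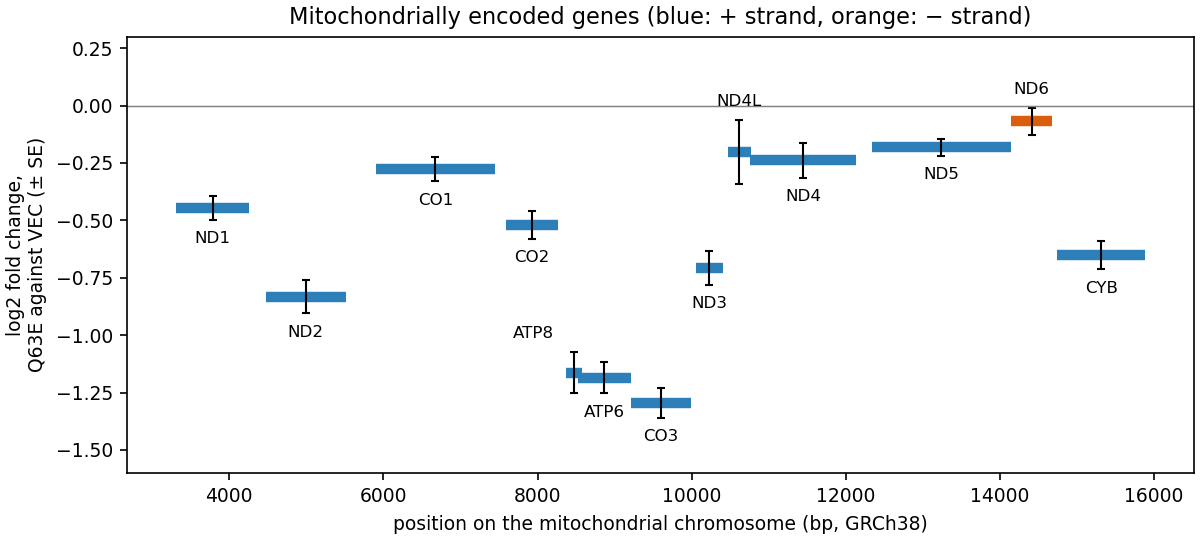
Log2 fold change (vertical axis, Q63E against VEC, error bars SE) of the 13 mitochondrially encoded genes at their positions on the mitochondrial chromosome (horizontal axis, bp), blue for genes on the plus strand and orange for the minus strand. MT-ATP8, MT-ATP6 and MT-CO3 lie lowest, between −1.16 and −1.29.

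Of 32 MRTF-SRF targets, genes of the contractile cytoskeleton, 12 rose and 7 fell (13 and 8 adjusted over the list alone, adjusted p = 0.398 in camera). TAGLN rose from 15.1 ± 1.57 to 45.2 ± 8.45, TPM1 from 80.3 ± 5.69 to 132 ± 7.49 and CALD1 from 34.8 ± 2.02 to 57.3 ± 1.75, while WDR1, in the lowered segment of chromosome 4, fell from 244 ± 5.16 to 151 ± 4.996.

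The following lists of matrix, adhesion and cell identity genes did not pass in camera. Of 39 extracellular matrix genes 15 rose and 14 fell (16 and 14 adjusted over the list alone, adjusted p = 0.433). COL8A1 rose from 8.48 ± 0.411 to 22.4 ± 2.12 and COL4A6 fell from 5.47 ± 0.630 to 1.72 ± 0.0723. Matrix proteases and inhibitors had 5 risen and 10 fallen of 27 (5 and 11, adjusted p = 0.349), with TIMP3, a protease inhibitor, at 3.83 ± 0.38 in VEC and 0.147 ± 0.0416 in Q63E. Integrin and focal adhesion genes had 6 risen and 9 fallen of 35 (10 and 9, adjusted p = 0.775). L1CAM rose from 82.0 ± 2.31 to 197 ± 13.8 and ITGA2 fell from 26.6 ± 1.59 to 14.1 ± 1.35. Angiogenic factors had 8 risen and 5 fallen of 23 (8 and 6, adjusted p = 0.479), with EDN1 (endothelin 1) higher at 10.5 ± 1.04 against 2.57 ± 0.360. Mesenchymal genes had 6 risen and 4 fallen of 14 (6 and 4, adjusted p = 0.479). WNT5A rose from 0.273 ± 0.0839 to 1.76 ± 0.266, while SPARC fell from 107 ± 2.49 to 70.7 ± 3.45. Urothelial differentiation genes had 3 risen and 0 fallen of 8 (3 and 1, adjusted p = 0.349), and these were ERBB3 (1.42 ± 0.205 to 4.77 ± 0.324), PPARG (13.2 ± 0.619 to 21.3 ± 0.25, in the raised segment of chromosome 3) and ERBB2 (29.9 ± 0.720 to 35.2 ± 0.774).

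The following lists of signalling and stress genes did not pass in camera. Immediate early and ERK feedback genes had 4 risen and 10 fallen of 28 (5 and 12 adjusted over the list alone, adjusted p = 0.293, and 0.0446 without VEC replicate 1), with JUNB lower at 17.4 ± 0.182 against 36.0 ± 4.78. TGF-beta and SMAD targets had 3 risen and 7 fallen of 21 (4 and 7, adjusted p = 0.296), with TGFBI lower at 10.9 ± 0.570 against 35.1 ± 2.32. Notch and Wnt targets had 3 risen and 3 fallen of 14 (3 and 5, adjusted p = 0.867). The Notch ligand gene JAG1 fell from 9.90 ± 0.526 to 3.16 ± 0.355, and MYC rose from 43.8 ± 3.88 to 61.9 ± 1.89. Stem cell-associated genes had 3 risen and 3 fallen of 12 (3 and 4, adjusted p = 0.886). The p53 targets had 2 risen and 4 fallen of 27 (2 and 4, adjusted p = 0.124, and 0.0318 with no filter on low values), and apoptosis regulators 2 risen and 5 fallen of 32 (2 and 5, adjusted p = 0.146). PMAIP1, on both lists, fell from 102 ± 5.94 to 49.8 ± 3.18. Amino acid response and ATF4 targets had 6 risen and 6 fallen of 29 (7 and 8, adjusted p = 0.464), with CHAC1 lower at 8.23 ± 1.10 against 23.1 ± 1.247. NRF2 targets had 7 risen and 5 fallen of 23 (8 and 5, adjusted p = 0.499). TXNRD1 rose from 308 ± 7.60 to 410 ± 16.2 and HMOX1, in a lowered segment of chromosome 22, rose from 46.3 ± 2.52 to 66.5 ± 3.16.

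Among metabolic and housekeeping lists that did not pass in camera, cholesterol genes had 2 risen and 9 fallen of 24 (5 and 9 adjusted over the list alone, adjusted p = 0.349). SQLE fell from 28.3 ± 1.57 to 19.7 ± 0.918. Fatty acid synthesis genes had 3 risen and 1 fallen of 16 (3 and 1, adjusted p = 0.323), with SCD (stearoyl-CoA desaturase) up 3.02-fold from 18.3 ± 0.968 to 55.1 ± 4.28. Autophagy and lysosome genes had 5 risen and 7 fallen of 34 (6 and 12, adjusted p = 0.349), and MAP1LC3A fell from 4.73 ± 1.15 to 0.0800 ± 0.0436. Proteasome subunits had 2 risen and 3 fallen of 31 (1 and 1, adjusted p = 0.886). Replication-dependent histones had 0 risen and 1 fallen of 8 (0 and 0, adjusted p = 0.867), and H2BC12 had 16 ± 3.21 in VEC and 13.6 ± 2.38 in Q63E. Of the markers of other cell types, 1 of 17 leukocyte markers (CD68, which fell from 18.5 ± 0.909 to 10.1 ± 0.879), 2 of 13 fibroblast and smooth muscle markers and 0 of 11 endothelial markers reached the minimum mean. The 2 were ACTA2, which fell from 6.46 ± 0.610 to 4.06 ± 0.169, and COL1A1, at 1.30 ± 0.155 in VEC and 2.21 ± 0.561 in Q63E. The median, the mean and the direction in camera differed in sign for extracellular matrix, angiogenic, NRF2, Notch and Wnt, stem cell-associated, proteasome and histone lists.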

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

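The loci without a gene name, which the comparisons above left out, also held differences between the groups. Of 479 such loci with a mean of at least 1, 17 were higher and 26 lower in Q63E than in VEC in limma, fitted together with the genes. The locus with the largest rise had a mean of 11.6 in VEC and 27.1 in Q63E (log2 fold change 1.19, adjusted p = 0.0229). The locus with the largest fall had 65.5, 44.7 and 44.9 in the VEC libraries and was listed at 0 in each Q63E library. Several more of the lower loci were listed at 0 in each Q63E library, while the higher loci were above 0 in every VEC library. A value of 0 can be a failed estimate, so part of the falls may not be real.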

How the results depend on the processing

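The shifted-segment, unnamed-locus and listed-at-0 alternatives were chosen after seeing the data. RHOC passed in every fit that held it, at log2 fold changes of 2.67 to 2.98, with 2.91 to 2.95 when each library was left out in turn. RHOC lies in a shifted segment and has no value without them. Leaving out each library gave 2350 to 2630 changed genes, 994 to 1153 higher, 1325 to 1477 lower, 306 to 336 changed 2-fold and 11 to 13 lists. At a threshold of 0.01 there were 1618 changed genes (645 higher, 973 lower), and tested against 1.5-fold 182. With a pseudocount of 0.1, 475 genes changed 2-fold (320 shared). With the replicate number as a block there were 2208 (2133 shared), 942 of them higher. Same-numbered libraries deviated with r of −0.0419, −0.00866 and −0.0249 across genes. These values give no sign of pairing, but with 3 libraries per group they cannot exclude a shared culture or day. Without the shifted segments 1162 genes were lower, and without those genes 10 of the 12 lists passed. More genes were higher than lower with upper-quartile scaling (1868 and 1630) and with equal totals (1832 and 1587), unlike the 1510 and 1873 reported, and the median log2 fold change of all genes was then 0.0295 and 0.0308.

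With an estimated correlation 0 lists passed, and 25 with fry, which asks another question. For the 159 named genes, 2513 of 2651 values kept their direction and side of the threshold, 133 no longer passed and 5 reversed. With segments centred RHOA had −0.0607 and PFKFB3 0.0934. With each library left out, the histone genes HIST2H2AA3 (−1.385 to 0.146) and H4C8 (−0.01855 to 2.414) reversed, and neither passed in any fit. Of the 45 named genes inside shifted segments, 19 lost their call when centred. DESeq2 and limma-voom were not run because the values are not counts. Read depth is unknown, so its effect on precision is too.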

Other observations

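The tests of scaling, of an equal fall of the mitochondrial genes and of the list members outside the shifted segments were chosen after the results were seen, as were the genes of the next 2 paragraphs and the gene families.

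Of 11 other tested genes within 400 kb of RHOC, 6 passed, all of them higher in Q63E. In the raised segment that holds them 40 of 81 tested genes were called higher and 3 lower, so this count is near the segment's own share. MOV10, an RNA helicase gene that ends 360 bases from RHOC and runs toward it, rose from 32.4 ± 4.71 to 92.1 ± 8.76 (SD, n = 3, 2.84-fold, log2 fold change 1.48, adjusted p = 0.000441 in limma). The next gene on that side, CAPZA1, rose 1.23-fold from 95.2 ± 0.892 to 117 ± 3.70, close to the raised segment around it, whose median ratio was 1.23. On the other side PPM1J had 1.74 ± 0.309 in VEC and 2.37 ± 0.787 in Q63E and did not pass (adjusted p = 0.389). ENSG00000271810, an unnamed gene model that overlaps RHOC on the same strand, was listed at 0 in all VEC libraries and had 3.42, 3.73 and 3.31 in Q63E.

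A set of 15 genes was near absent in one group (mean under 1) and had a mean of at least 5 in the other, 10 of them present in VEC and 5 in Q63E. Besides genes named above, FABP4, a fatty acid binding protein gene, went from 7.44 ± 0.802 to 0.75 ± 0.408 and FAM43A from 5.19 ± 0.656 to 0.343 ± 0.0404, while CACNA2D3, a calcium channel subunit gene, went from 0.790 ± 0.244 to 5.05 ± 0.745. For 12 of the 15, each library of the higher group exceeded 5 times each library of the lower group. KIRREL3, among these 12, had 2.88, 3.21 and 21.41 in the Q63E libraries, so it reached the mean of 5 through 1 library. For 3, an overlapping gene had at least the lost value in the group that lacked them. Overlap and failed estimates were tested as explanations of these 15 genes, and overlap was left undecided. A failed estimate would be listed at 0. SEPTIN1, FZD8, CYB5R2, FABP4, FAM43A, NPPB, KIRREL3, CACNA2D3 and ENSG00000250038 were above 0 in each library of the lower group. That argues against failed estimates for them. TMC2, SNRPGP15, ENSG00000261090 and ENSG00000258638 were listed at 0 in each, so failed estimates stay open there. TMPRSS15 (0, 0.05 and 0.01 in VEC) and ENSG00000248235 (0.15, 2.21 and 0 in Q63E) were listed at 0 in 1 library of the lower group. For those 2 genes a failed estimate stays open for that library only. Among 297 families of genes with a shared symbol stem and at least 6 members, 3 passed in camera, CXCL (0 risen and 6 fallen of 7, adjusted p = 0.000489), IFI (0 risen and 4 fallen of 9, 0.0109) and MT-ND (0 risen and 4 fallen of 7, 0.0494). With an estimated correlation 0 families passed in camera. The 3 families share genes with the NF-kB, interferon-stimulated and mitochondrially encoded lists, so they add no separate support to those lists. CXCL1, CXCL3, CXCL6 and CXCL8 lie in the lowered segment of chromosome 4.

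Genes that moved together along whole chromosome parts are the first pattern to weigh. Of 426 windows of 50 neighbouring protein-coding genes, 47 had a median of 0.25 or more in size, and in 1000 shuffles of gene order the highest number was 0. The median ratios of the 6 lowered segments ran from 0.747 to 0.821 and those of the 2 raised ones were 1.23 and 1.26. Every Q63E library lay outside the range of the VEC libraries, which follows largely from choosing the segments by their group difference. A candidate explanation is a difference in DNA copy number between the cultures, which may have come with the outgrowth of few cells under selection. The window counts and the ratios are compatible with it. Copy number was not measured, regional regulation was not tested separately, and an effect of active RhoC itself stays open.

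The second pattern is the joint fall of NF-kB, cytokine and interferon-stimulated genes. RNA of leukocytes in VEC was tested as a source too. Only 1 of 17 leukocyte markers reached the minimum mean (CD68, log2 fold change −0.82), which argues against that source. The scalings tried do not account for the joint fall, since the highest median of the 2 lists' members over 3 scalings was −0.566. Their factors ran only from 0.9756 to 1.032, so they could not have moved that median far. Without the 6 chemokine genes on chromosome 4 the rest of the NF-kB list had a median of −0.600, and the 54 members of both lists outside the shifted segments had −0.557, so neither the cluster nor the segments account for the whole. An effect of active RhoC stays open and was not tested, as does a difference between the 2 transduced populations that arose apart from RhoC.

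The third pattern is the unequal fall of mitochondrially encoded genes. Reads moved to nuclear copies cannot account for it, because the length-weighted value of 404 such copies changed by −1.71% of the loss, and the most abundant, MTATP6P1 (named outside the rule for naming genes), had 609 in VEC and 260 in Q63E. Scaling left a highest median of −0.483 over 3 scalings, whose factors of 0.9756 to 1.032 could not have moved it far. A fall alike for every mitochondrial gene is not the whole cause, since the log2 fold changes of the 13 genes ran from MT-CO3 to MT-ND6 (−1.29 to −0.07) with an SD of 0.418 against a largest SE of 0.14. The values also argue against 1 equal fall of the other genes beside a further one of MT-ATP8, MT-ATP6 and MT-CO3, which lay lowest. MT-ND2, MT-ND3 and MT-CYB had −0.83, −0.71 and −0.65 (SE 0.072, 0.073 and 0.062). MT-CO1, MT-ND5 and MT-ND6 had −0.28, −0.18 and −0.07 (SE 0.054, 0.037 and 0.058). The rest of the other genes lay between MT-CYB and MT-ND6. Apart from MT-ND2, these genes are named outside the rule for naming genes. An overall fall beside further, unequal ones stays open. A change in the neighbouring MT-ATP8, MT-ATP6 and MT-CO3 transcripts themselves, a mitochondrial sequence variant of 1 culture and a difference in library preparation may each contribute and were not tested.

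With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3383 changed genes and 324 changed 2-fold, and the highest other split gave 0 of each. It gave 12 lists, and the highest other split 7. In each of these counts 1 of the 10 splits, the real one, was as large. Every other split has libraries of both groups on both sides, so the difference between the groups adds to its spread. The 0 calls of those splits therefore do not measure how many of the 3383 genes could be false.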
